A study of Mus musculus with 8 samples.

How the data were processed

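Hearts were perfused and excised, and total RNA was enriched for small RNA and labelled at its 3' end with a single dye, per the labels' protocols. The groups, the replicate numbers and the assignment of 6 blocks of a slide to each mouse come from the sample labels. The design text says that the samples are 8 separate mice.

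The deposited scanner files hold foreground and local background intensity per spot, as the median pixel on a linear scale. Per the file headers, they were exported from GenePix Pro 4.1.1.4 after a scan on a GenePix 4000B at 1 wavelength with the same detector gain on both slides, and the software applied no normalization. Spot flags in the deposited files, another kind of column, took no value that marks a bad spot, so no spot was left out for its flag. However, between 2187 and 2760 of the 4860 spots per array were flagged as not found, and 108 as absent, and these spots were kept. A filter on flag 0 left 635 probes for testing, with 0 called by limma. The authors' value table holds linear intensity for 318 probes; its scaling and background steps are not given in the sources used here. Each of its columns correlated best with the scanner values of its own array (r from 0.993 to 0.999 on the log2 scale, across probes); across probes below the ceiling with a background-subtracted signal over 200, the slope of log2 table value on log2 scanner value was 0.993 to 1.02. In that range the values were near proportional to the scan; the cause of the departures at the dim and bright ends stays unknown. Its medians were 458, 477.5, 484 and 488 for LPS replicates 1 to 4 and 462.5, 542.5, 441.5 and 484.5 for saline replicates 1 to 4.

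Each array held 4860 spots: 4707 probe spots, 108 unnamed spots, 36 spots named NONE and 9 Ncode control spots. Background was corrected on all spots with the normexp model and an offset of 50 (limma 3.58.1 in R 4.3.3). The log2 values of a probe's 3 spots were averaged, and the probes were quantile normalized between arrays without the control spots. A probe counted as detected on an array when at least 2 of its 3 spots exceeded the 95th percentile of the unnamed and NONE spots, which lay between 66.85 and 77 intensity units. This limit replaced a rule based on the spread of the local background, for which no column was used. Detection on all 4 arrays of at least 1 group was required. Differences were tested with limma (lmFit and eBayes) without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Intervals are at 95% and are not adjusted for the number of probes. Single values per array were compared by an exact permutation test over the 70 assignments of 8 arrays.

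The alternatives were fixed before the data were examined, except for those that the closing section lists as chosen after seeing the data. The design and the rule for named probes were also fixed beforehand. The rule takes the probes with the largest changes among those past the threshold or, where fewer than 5 pass in a direction, the 5 with the smallest p; because the codes are not paired with microRNA names, only the first 2 in each direction are named. The rule also asked for chosen microRNAs by name and for members of 15 lists. Those parts, the tests of the lists, and the restriction to mouse probes could not be applied to probe codes and are not reported here. All named probes were used instead. The alternatives changed the background correction, normalization, filter, spot summary, test, threshold and set of arrays, and used the authors' table; their effect is given in the closing section.

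The calculation was tested on simulated data made from the residuals of these arrays over 1256 probes, with 200 probes changed. For the comparison of LPS with saline, 87.0% of 1.5-fold, 96.1% of 2-fold and 99.0% of 3-fold changes were called (means of 20 repeats), with 5.91%, 5.29% and 2.91% false calls. With no probe changed, 0 of 20 repeats gave a call. Of the 35 splits of the real arrays into equal groups, however, 2 gave calls, with up to 52. The simulated null therefore does not hold all the structure of these arrays. The recovered shares hold for 200 changed probes, and with few changed probes the adjusted threshold is harder to pass. The changes were added to the normalized log2 values, after the offset. The shares therefore leave out the shrinkage of dim probes by the offset and do not give the recovery of such changes in RNA amount.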

Results

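Low-molecular-weight RNA from the hearts of 8 female C57BL/6 mice, a common inbred laboratory strain, was profiled on 1-colour microRNA arrays. MicroRNAs are short RNAs that lower the output of target messenger RNAs. The mice were 12 weeks old. Of these, 4 had received lipopolysaccharide (LPS, a bacterial cell wall component that triggers inflammation) at 5 mg per kg into the abdominal cavity 8 h earlier, and 4 had received saline. Each mouse gave 1 array. Each array held 1569 named probes in 3 spots each. The deposited files identify these probes by array codes and do not pair them with microRNA names, so the results are given by probe code. All 4 LPS arrays lay on 1 slide and all 4 saline arrays on another, so slide and treatment cannot be told apart in any value below.

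The mean probe foreground was 1359 ± 163 intensity units on the LPS arrays and 1350 ± 153 on the saline arrays (SD, n = 4 each; exact two-sided permutation p = 0.857). The median local background was 62.0 ± 0.816 on the LPS arrays and 68.0 ± 2.16 on the saline arrays (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays can give). All arrays of a group share a slide, so this p does not measure the spread between slides. Between 1208 and 1490 probes per array were detected, and 1256 probes were detected on all 4 arrays of at least 1 group and were tested. The number of arrays limits the precision of each comparison.

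The comparison of LPS with saline asked which cardiac microRNAs differ 8 h after the injection. Cardiac profiles of the 2 groups were close: across tested probes, the correlation between an LPS and a saline array ranged from 0.982 to 0.997, against 0.994 to 0.998 between LPS arrays and 0.985 to 0.995 between saline arrays. These correlations are across probes, which are not independent replicates. No probe passed an adjusted p of 0.05 in limma (0 higher and 0 lower of 1256; smallest adjusted p = 0.450). At an unadjusted p under 0.05, limma gave 69 probes higher and 59 lower in LPS, 128 in all, where chance would give 62.8 if no probe differed; the probes are correlated, so this is no limit for the count. An exact permutation test per probe gave 0 after adjustment and says little here, since its smallest p is 0.0286 and at least 718 separated probes would be needed for a call. In 69 probes (5.49%) the 4 LPS values lay entirely above or below the 4 saline values, where chance gives 2.86%. Control spots named Ncode were bright on replicates 1 and 3 of both groups (mean foreground 9170 to 11402) and near background on replicates 2 and 4 (68.8 to 73.2); these are named here the arrays with and without Ncode signal. With this difference as a block, limma called 0 probes (135 at an unadjusted p under 0.05). Within the arrays with control signal it called 0 (73 unadjusted), and within those without it 0 (64 unadjusted). Saline replicate 4 stood apart from the other arrays, and without it the count was 0 (111 unadjusted). Without saline replicate 1, limma called 2 probes, 1 higher and 1 lower (192 unadjusted). The unadjusted count was 82 without LPS replicate 1 and 83 without LPS replicate 2, with 0 calls in each.

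Probe ORB_1209019 had the smallest p of all, but not the largest difference. Of the 1256 probes, 5 differed by over 2-fold, with a largest absolute log2 difference of 1.34. Among them, the probe with the third smallest p in the higher direction had 1.11 (SE 0.26, limma adjusted p = 0.450). The normalised log2 intensity of ORB_1209019 was 11.68 ± 0.27 in LPS and 10.69 ± 0.29 in saline (SD, n = 4 each), with all 4 LPS values above all 4 saline values. The log2 difference was 0.99 with a standard error of 0.18, or 1.99-fold (95% interval 1.49 to 2.66), at a limma adjusted p of 0.450. The difference was 0.91 within the arrays with Ncode signal and 1.08 within those without. In the same direction, probe 2996 had the next smallest p, with a log2 difference of 0.18 (SE 0.04; limma adjusted p = 0.450). Its values were 6.47 ± 0.07 in LPS and 6.29 ± 0.03 in saline (SD, n = 4 each), and its difference was 0.12 and 0.23 within the arrays with and without Ncode signal. The probe is dim (mean foreground 93.1 in LPS and 83.8 in saline), and its log2 difference was 0.52 with plain background subtraction and 0.30 with an offset of 16. Plain subtraction sets signals under 16 to 16. With a median local background of 68.0 on the saline arrays, the probe's saline signal lay near this floor, which may shape the 0.52.

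In the other direction, probe IDT_1583 had log2 intensities of 8.97 ± 0.13 in LPS and 9.47 ± 0.17 in saline (SD, n = 4 each). Its log2 difference was -0.51 (SE 0.09; limma adjusted p = 0.450), with -0.58 within the arrays with Ncode signal and -0.44 within those without. Probe ORB_0908023 had 7.19 ± 0.09 in LPS and 7.44 ± 0.08 in saline (SD, n = 4 each). Its log2 difference was -0.25 (SE 0.06; limma adjusted p = 0.450), and -0.34 and -0.16 within the arrays with and without Ncode signal. With plain background subtraction it was -0.40. All 4 LPS values of both probes lay below all 4 saline values. With the block, which is balanced over the groups and so cannot move a difference, the limma adjusted p was 0.438 for each of the 4 probes. Under other settings ORB_1209019 passed with cyclic loess (limma adjusted p = 0.0436) and IDT_1583 with scaling on the median of probes detected on all 8 arrays (limma adjusted p = 0.0471).

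**Figure D1:**
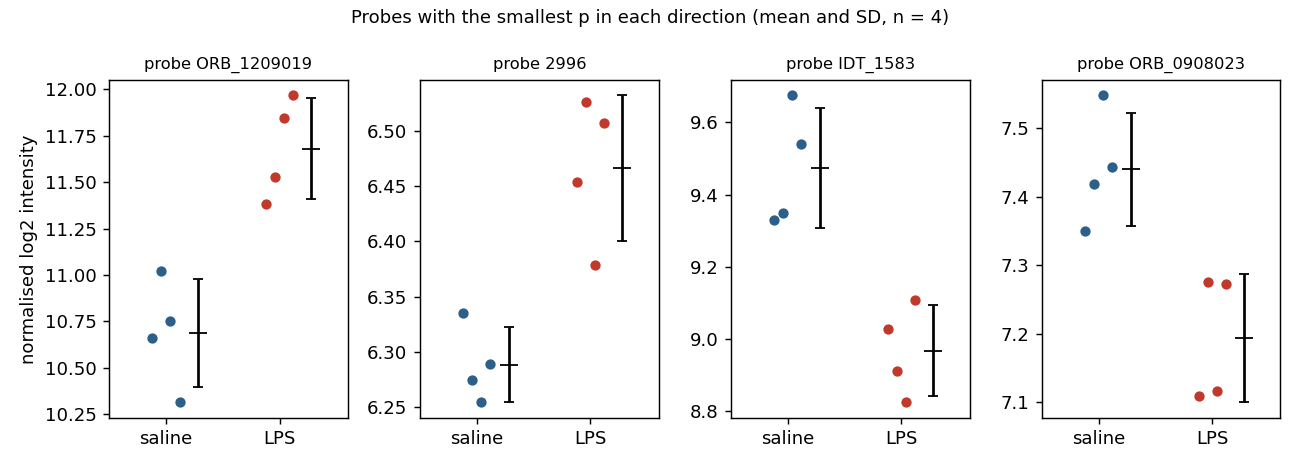
Normalised log2 intensity of the 2 probes with the smallest p in each direction, with 1 point per mouse and the mean and SD of each group (n = 4) beside the points. In each probe the LPS and saline points do not overlap. Of the 4 probes shown, ORB_1209019 has the widest difference between group means, 0.99 on the log2 scale, and none passed the adjusted threshold.

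The intervals bound the size of change that these arrays leave open. For 1220 of the 1256 probes (97.1%), the 95% interval of the difference lay within 2-fold in either direction, and for 1115 (88.8%) within 1.5-fold. The offset added to each signal shrinks the differences of dim probes. Among the 253 probes with a mean log2 intensity over 8, the interval lay within 2-fold for 230 (90.9%) and within 1.5-fold for 173 (68.4%). The 5 brightest probes in saline, which are among these 253, were saturated in 114 of their 120 spots and give no measure of change. Between 18 and 25 probe spots per array were saturated, so other probes held saturated spots too. Such probes were not left out of these counts.

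The authors' value table holds 318 of the probes for the same 8 arrays, all of them detected on all 8 arrays in the deposited scan. On the log2 scale, limma called 13 of these probes higher and 53 lower in LPS. After quantile normalization of the table, an alternative chosen after seeing the data, it called 5 higher and 2 lower. The scanner values of the same 318 probes gave 0 calls (40 at an unadjusted p under 0.05). ORB_1209019 had 7782 ± 972 intensity units in LPS and 3434 ± 535 in saline in the authors' table (SD, n = 4 each), a log2 difference of 1.19 (SE 0.16; limma adjusted p = 0.00656). ORB_0908023 had a log2 difference of -0.58 in that table (SE 0.16; limma adjusted p = 0.0333). Probe 2996 had 0.29 (SE 0.14; limma adjusted p = 0.165) and was not called, and IDT_1583 was not among the table's probes. All 13 probes called higher in the table had a positive difference in the scanner values as well, with medians of 0.76 in the table and 0.34 in the scanner values. The 53 called lower had a median of -0.67 in the table, and 29 of them had a negative difference in the scanner values.

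The table's highest value differed between the groups. It was 50038 ± 9241 on the LPS arrays and 86902 ± 7506 on the saline arrays (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest possible). Between 21 and 27 probes per LPS array and between 8 and 13 per saline array lay within 1% of that highest value. These were reached at scanner signals from 20952 ± 3050 on the LPS arrays and from 42615 ± 4283 on the saline arrays. For dim probes, the ratio of table to scanner value, relative to that of brighter probes, was 0.842 ± 0.0309 in LPS and 1.21 ± 0.0371 in saline (SD, n = 4 each; exact two-sided permutation p = 0.0286). The permutation p of the highest value and of this ratio compare the arrays of 1 slide with those of another. They do not measure the spread between slides. In the dimmest sixth of the table's probes the median log2 difference was -0.39 in the table and 0.02 in the scanner values. In the brightest sixth it was -0.19 and 0.02. Sixths 4 and 5, counted from the dimmest, went the other way in the table, with medians of 0.09 and 0.17. Their scanner medians were 0.06 and 0.06.

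**Figure D2:**
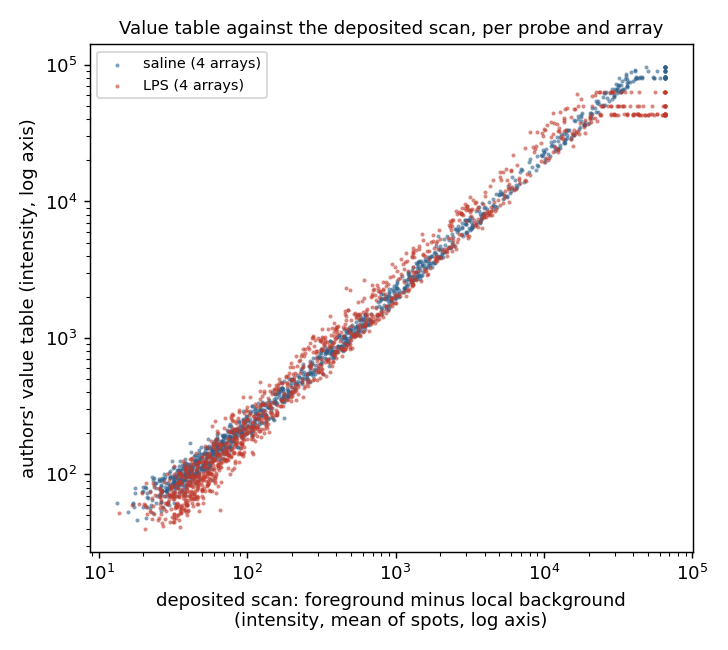
Value of each probe in the authors' table against its background-subtracted intensity in the deposited scan, both on log axes, with 1 point per probe and array and 4 arrays per group. The LPS arrays level off between 42996 and 63012 and the saline arrays between 80276 and 96076.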

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

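The counts of splits for the scanner values, those over balanced splits, the block on the exchanged split and the tests of overall signal and control signal for saline replicate 4, of the control batch for the split of arrays, and of the ceiling and the treatment for the authors' table were chosen after the result was seen; the others in this part were set down first.

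The mean correlation of saline replicate 4 with the other arrays was 0.986, against 0.993 to 0.994 for the other saline arrays, which put it far from its group. Of 16 groups of 4 values examined this was the single such case, and chance marks about 1 in 20. On the first principal component (50.1% of the variance) it lay at 9.93. A defect in part of the slide is argued against by a highest block at 1.57 times the median block. Low signal stays open. LPS replicate 4, with a mean foreground of 1164 against 1175, lay at 0.30, far below saline replicate 4. It was nevertheless the highest of the LPS arrays on this component, with the others between -4.27 and -2.84. A missing control signal stays open too, since the other 3 arrays without it had a median of 0.30 (-3.91 to 2.74), against -2.55 (-4.27 to 0.32) for the arrays with it; no biological explanation was tested.

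The authors' table gave 66 calls, more than any of the other 34 splits of the 8 arrays (highest 28, with 1 of 35 splits giving as many). This argues against chance alone, though 1 of 35 is the smallest share that these splits can give. The real split is also the split by slide, so the count cannot tell treatment from slide. For the 6 lower calls at the table's ceiling with no saturated spot, the median log2 difference was -0.64 in the table and 0.044 in background-subtracted scanner values, so a lower ceiling on the LPS arrays may account for them. For the 8 lower calls at the ceiling that had saturated spots, 79.7% of the spots were saturated in the deposited scan too, and a change beneath the ceiling cannot be told apart from none. For the 39 lower calls below the ceiling, the medians were -0.63 in the table and -0.11 in background-subtracted scanner values. An offset of dim values that differs between the slides may account for this. Treatment as the whole of the difference is argued against by their lower quartile of -0.25 in the same subtracted values. Still, 9 of them had an unadjusted limma p under 0.05 in the same direction in the main fit, whose scanner values were processed differently. For the 13 higher calls the scanner median was 0.34 (0.28 in background-subtracted values), under 0.5 times the table's 0.76 but above 0.1, and treatment stays open.

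In the scanner values the real count was 0, which 35 of 35 splits reach by construction, so it says nothing about chance; for the 128 probes at an unadjusted p under 0.05, 3 of 35 splits gave as many (highest other 246), and chance cannot be excluded. The split that exchanges LPS replicate 4 and saline replicate 1 was the highest of the others, with 52 calls (next highest 1), and it sets 3 arrays with control signal against 1. The Ncode control batch as its whole cause is argued against, since the split by control signal gave 0 calls. With the signal as a block, the exchanged split gave 25 calls. Quantile normalization is argued against, since the other normalizations gave at least 30 calls on this split. Exchanged labels stay open: the labels as given separated 69 probes without overlap, against a median of 27.5 and a highest of 160 in the other splits, and 3 of 35 splits separated as many. Seen afterwards, the exchanged split also follows the first principal component. LPS replicates 1 to 3 and saline replicate 1 lay between -4.27 and -2.26 on it, and the other arrays between 0.30 and 9.93. What sets this component was not tested, so exchanged labels are not the only explanation left for the 52 calls. Among the 18 splits balanced for control signal the real labels were highest (69 separated, next 52; 128 at an unadjusted p under 0.05, next 111), but 18 splits are too few for a share under 0.05. In the authors' table the exchanged split gave 28 calls against 66 for the labels as given, which are also the split by slide.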

How the results depend on the processing

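The control signal as a block or within batches, the table's probes in scanner values, the table after quantile normalization, the filter on spot flags and the other detection limits were chosen after seeing the data. The count of called probes was 0 in limma and 0 under 26 of 32 alternatives. It was 2 with scaling on the median of probes detected on all 8 arrays, 1 with cyclic loess, 66 in the authors' table, 7 in that table after quantile normalization and 128 at an unadjusted p under 0.05; apart from the threshold, which admits more probes by construction, and the table, weighed above, the cause was not tested. Some of the 26 alternatives with 0 calls could give nothing else. An adjusted p under 0.01 and an added limit of 1.5-fold only narrow a fit with 0 calls. The exact permutation test per probe needed at least 718 separated probes for a call. Leaving out each array gave 0 to 2 calls, with 2 only without saline replicate 1. The median difference over the scanner probes was 0.01 (log2), 0.03 without normalization and 0.04 over the table's probes. With the replicate block the count was 0 (161 at an unadjusted p under 0.05). The correlations computed to check pairing of same-numbered arrays were 0.44, -0.09, 0.14 and 0.35. They are another measure than the array correlations given above, which were at least 0.982 for LPS and saline pairs. Not all of these 4 values were over 0.1, so the numbers were not taken to pair the mice. Still, 3 of 4 LPS and 2 of 4 saline arrays correlated best with their own number, and same-numbered arrays share their place on the slide and their control signal. The 4 named probes, picked for their small p in these arrays, kept their direction in all alternatives run for them. Their LPS and saline values do not overlap. The direction was therefore fixed in advance wherever arrays were only left out or weighted, a block added or the filter changed. ORB_1209019 passed in 3 of 28 (log2 difference 0.86 to 1.19), IDT_1583 in 1 of 25 (-0.62 to -0.44), ORB_0908023 in 1 of 28 (-0.58 to -0.16) and 2996 in 0 of 28 (0.12 to 0.52, highest in the quantile-normalized table and with plain subtraction). Scaling on control spots was not run, since these were near background on 4 arrays; nor were the tests of microRNA lists (camera and fry), probes of all species, flagged spots kept (no spot was marked bad), a slide block (each slide held 1 group), or detection by 3 SD of the local background. Probes near background limit the detection count: its median per array was 1394, 1025 with the mean of blank spots plus 3 SD and 723.5 by spot flag.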

Other observations

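The tests in this part were chosen after the probe names or differences were seen, except for the count of splits.

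Some probe codes share a number after different prefixes (22 pairs of tested probes) or with and without a suffix (3 pairs). Over these 25 pairs from 11 shared numbers, the log2 differences of the pair members correlated at 0.78 across pairs, above 100% of 10000 random pairings matched on intensity (random median -0.04, 95th percentile 0.37) and above 100% of 10000 random pairings within the same prefix (median 0.06, 95th percentile 0.39). Pairs from 1 number are not independent, and probes are not independent replicates. A candidate explanation is that probes that share a number measure the same target; the files do not state it.

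Groups of probes by the start of their code were set against all other probes with camera. With a preset correlation of 0.01, 5 of 14 groups passed an adjusted p of 0.05, and 6 with the Ncode control signal as a block. With an estimated correlation 0 passed (smallest adjusted p = 0.162). As many groups passed in 9 of 35 splits of the 8 arrays, with up to 9 groups in another split, so chance cannot be excluded. The group with the smallest preset p was IDT_, with 10 probes and a mean log2 difference of -0.17 (adjusted p = 0.000203 preset, 0.162 as the p with an estimated correlation; -0.20 and -0.13 within the arrays with and without control signal).

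The Ncode control spots had mean foregrounds of 9170 and 10299 on LPS replicates 1 and 3 and 11402 and 9990 on saline replicates 1 and 3. On LPS replicates 2 and 4 they had 68.8 and 70.2, and on saline replicates 2 and 4 they had 72.9 and 73.2.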
